A study of Mus musculus with 10 samples.

How the data were processed

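Total RNA from the hippocampus of male C57BL/6 mice aged 30 months was measured on Affymetrix oligonucleotide arrays, with 1 mouse per array, 5 mice on a control diet and 5 on long-term calorie restriction. Per the labels' protocols, RNA was extracted with Trizol and turned into biotin-labelled cRNA. The deposited table holds 12488 probe sets, each a group of short probes for a transcript, with 1 intensity per array on a linear scale. The authors computed these intensities with MAS5, per the submitters' processing notes; its version and settings are not given in the sources used here. MAS5 summarises the probes of a set within an array and scales the whole array to a common target. In the deposited intensity values, the mean with the lowest and highest 2% left out was 500 on each array, so differences in overall brightness between arrays had been removed before deposit. Raw image files and detection calls were not analysed here.

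Values under 1 (41 of 124880) were set to 1 and all values were taken to log2. The 66 Affymetrix control probe sets were left out of the tests and used as measures of RNA and array quality. Of the other 12422 probe sets, those with a mean log2 signal below the 40th percentile were left out, which left 7453. Gene names came from the platform's annotation table. It gave 1 symbol for 10833 probe sets, several for 396 and none for 1193; 10817 of those with 1 symbol were matched to RefSeq by gene number. Probe sets with several symbols were not named. No positions on the genome are printed, since the build behind the probe sets is not given in the sources used here. Probe sets with s, f, i, r or g in their identifier can match several transcripts or rest on fewer probes.

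Diets were compared in limma 3.58.1 under R 4.3.3 with lmFit and eBayes, using a trend of the variance on the mean and no other term. A probe set passed at a Benjamini-Hochberg adjusted p under 0.05 over the 7453 tested. Changes are calorie restricted minus control on the log2 scale, and are given relative to the median change of all tested probe sets, which was -0.15. Standard errors (SE) come from the same fit. The limma p-values of probe sets and genes, and the calls of higher or lower, test the change against 0 before this median is taken off. They do not test the relative values printed beside them, and a fall passes more easily than a rise of the same printed size. Gene lists were tested with camera at a preset correlation between genes of 0.01, using for each gene the probe set with the highest mean. Of 50 lists fixed before the data were examined, covering cell types, neighbouring tissues and pathways, 45 had the 5 genes needed. Their p-values were adjusted over the 45 lists. The test was repeated with an estimated correlation, and fry was run on the same lists. Array measures were compared with an exact two-sided permutation test over all 252 splits of the arrays into 5 and 5, whose smallest possible p is 0.00794. The number of arrays limits the precision of every comparison.

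The design and the rule for naming genes were fixed then too. The rule takes the 12 higher and the 12 lower genes with the smallest adjusted p and a change of at least 0.26. It adds up to 4 members of each list with the smallest p, any member past the threshold in a list that passed, and the control and sex check genes. It gives 211 genes. Besides control and sex check genes, the text names 97 of these, picked for the groups it describes after their values were seen. Any gene named outside the rule is said to be so.

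In the same way, 14 other settings were chosen besides leaving out arrays; they changed the normalization, the filter, the offset, the variance model, array weights, a covariate for RNA quality, a replicate block, the threshold, the probe sets per gene and the list test. Each of the 10 arrays was also left out in turn. A further 4 alternatives were added after the data were seen: leaving out calorie restricted replicates 3 and 5, leaving out 3, 4 and 5, leaving out 3 and 5 under quantile normalization, and adding RNA quality and spike-in signal together as covariates. No scan dates or batches are given in the sources used here.

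The fit was tested on simulated data for this comparison with 7453 probe sets, of which 200 were changed. It recovered 2% of the 50 changed by 0.5 on the log2 scale, 30% of those changed by 1, 92% of those changed by 2 and 96% of those changed by 3. Among its 115 calls 5 were false, and 100% of the recovered ones had the right direction. In a simulation of 45 random lists, the list shifted by 1 was called and 0 others were. The simulated noise was independent between probe sets and had the same spread in both diets. These rates therefore do not cover correlation between genes or a spread that differs between diets.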

Results

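Hippocampal RNA of 10 male C57BL/6 mice aged 30 months was measured, from 5 mice fed a control diet and 5 kept on long-term calorie restriction. Each mouse was measured on 1 array. Correlation of log2 signals over probe sets ran from 0.902 to 0.937 between control arrays and from 0.826 to 0.904 between calorie restricted arrays. Between 1 array of each diet it ran from 0.810 to 0.916. Xist, transcribed from the inactive X chromosome of females, had a mean log2 signal of 5.17 ± 0.61 (SD, n = 5) in control and 4.77 ± 0.85 in calorie restricted mice. Among Y-linked genes Eif2s3y had 7.93 ± 0.52 and 8.61 ± 0.27, Uty 6.88 ± 0.73 and 5.64 ± 1.01, and Kdm5d 4.89 ± 1.32 and 4.10 ± 0.81; Uty, Kdm5d and Xist lay below the filter on signal.

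The main comparison asked which transcripts differed between diets. Transcripts for Tmsb10, an actin-binding thymosin, Sod1, the cytosolic superoxide dismutase, Gnb1, a G protein beta subunit, and Npy, an inhibitory neuropeptide, were higher in calorie restricted mice. Relative to the median change, they were higher 3.37-fold, 4.52-fold, 9.29-fold and 2.99-fold, with log2 changes of 1.75 ± 0.17, 2.18 ± 0.22, 3.22 ± 0.33 and 1.58 ± 0.21 (SE, n = 5 per diet). Transcripts for Ppp3cb, a calcineurin catalytic subunit, Fgf13, a fibroblast growth factor homologue that binds sodium channels, Btbd3, and Atp1b2, a sodium pump subunit of astrocytes, were lower. Their log2 changes were -1.86 ± 0.23, -2.04 ± 0.29, -1.84 ± 0.29 and -2.12 ± 0.35 (SE). The limma adjusted p was 0.00132 for Tmsb10, Sod1 and Gnb1, 0.00600 for Npy, 0.00204 for Ppp3cb, 0.00442 for Fgf13, 0.00523 for Btbd3 and 0.00648 for Atp1b2. Another probe set of Gnb1 had the opposite direction and did not pass.

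The other 8 genes among the 12 higher were Arglu1, Nipsnap2, Idi1, Myl12b, Atp5e, Rpl41, Pcnp and Lsm14b. Idi1, an enzyme of isoprenoid and cholesterol synthesis, changed by 1.60 ± 0.18 (SE) and Myl12b, a myosin light chain, by 1.54 ± 0.19. Rpl41, a ribosomal protein transcript whose probe set can match several transcripts, changed by 1.41 ± 0.17, and by 0.29 with a limma adjusted p of 0.236 under quantile normalization. The other 8 among the 12 lower were Cytip, Slpi, Ptbp2, Siah1-ps1, Rragd, Prcc, Scgb1b2 and Gm17811. Ptbp2, a splicing regulator of neurons, changed by -1.37 ± 0.21 (SE) and Rragd, a Rag GTPase of the mTOR pathway, by -2.37 ± 0.38. Slpi, a secreted protease inhibitor, changed by -0.96 ± 0.15, while another of its probe sets had the opposite direction. In all 24 genes, the signals of the 5 calorie restricted and the 5 control arrays did not overlap, and all 24 passed without calorie restricted replicates 3 and 5, whose RNA quality was lowest. These genes were picked for the smallest adjusted p on the same arrays, so neither result is independent support. For 9 of the genes named here, Fgf13, Cytip, Rragd, Gm17811, Atp1b2, Nxph1, Fgfr3, Ugt8a and Cacna1g, the mean of 1 diet lay below 6.85, the lowest mean log2 signal tested. Background was not analysed, so the size of these changes is uncertain. The direction of Cacna1g is not firm either, as it had -0.0070 with RNA quality and spike-in signal as covariates. The others kept their direction in every alternative that measured them. Still, the median log2 change of the dimmest 1491 tested probe sets was itself -0.42, in the same direction as their falls.

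**Figure D1:**
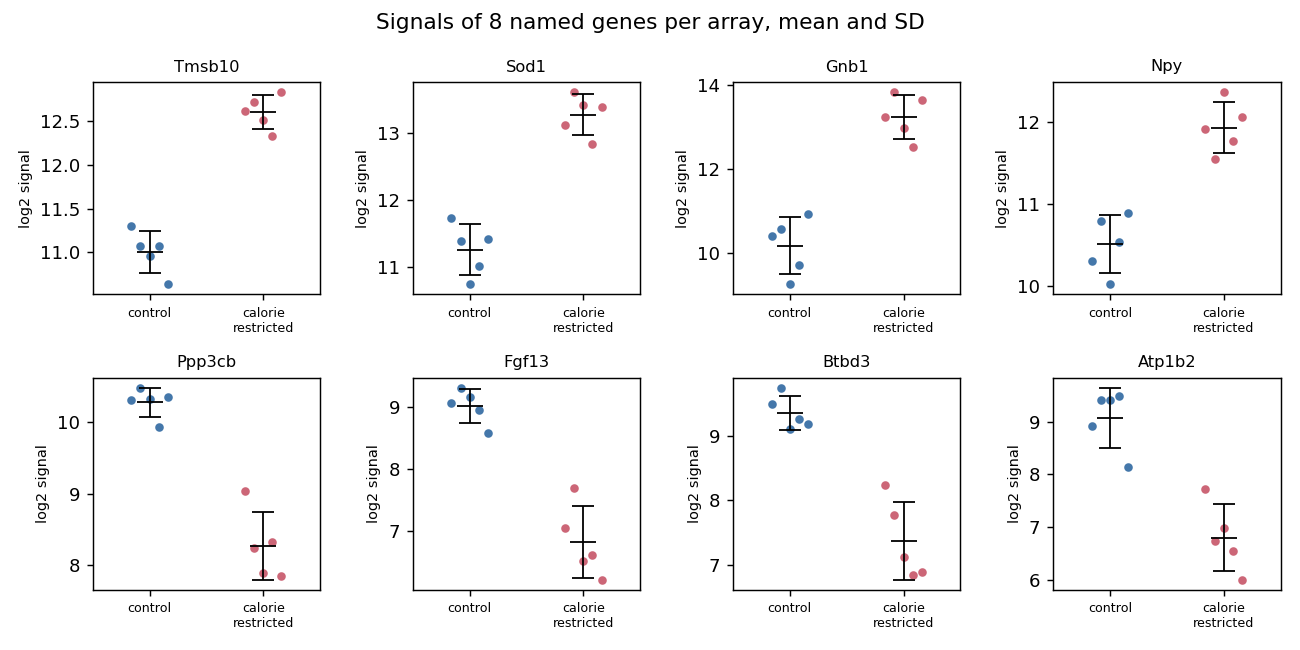
Log2 signals of 8 named genes, with 1 point per array, and the mean and SD of the 5 arrays of each diet as bars. For Tmsb10, Sod1, Gnb1 and Npy the calorie restricted arrays lay above all control arrays, and for Ppp3cb, Fgf13, Btbd3 and Atp1b2 below them.

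A second comparison asked whether RNA and array quality went with the diet. Control probe sets at the 3' and 5' ends of Gapdh and Actb, which encode a glycolytic enzyme and cytoplasmic actin, drift apart when RNA is broken or incompletely copied. The Gapdh 3' signal was 82.7 times the 5' signal in calorie restricted replicate 3 and 160.7 times in replicate 5, against 0.815 to 1.53 times in control mice. Replicates 1, 2 and 4 had 1.29, 1.24 and 1.98 times. For Actb the ratio was 2.32, 2.38, 16.4, 4.18 and 29.7 in calorie restricted replicates 1 to 5 and 1.05 to 1.61 in control mice. The log2 difference averaged over both genes was 2.88 ± 2.57 in calorie restricted and 0.16 ± 0.24 in control mice (SD, n = 5 each; exact permutation p = 0.00794, adjusted p = 0.0119 over 9 measures), with no overlap. The mean log2 signal of the bacterial spike-in probe sets was 13.05 ± 0.47 against 11.12 ± 0.56, a 3.79-fold difference, also without overlap (exact permutation p = 0.00794, adjusted p = 0.0119). Median log2 signal was 7.49 ± 0.18 in calorie restricted and 7.84 ± 0.05 in control mice (exact permutation p = 0.00794, adjusted p = 0.0119). The SD of log2 signals over probe sets was 2.57 ± 0.12 against 2.40 ± 0.06 (exact permutation p = 0.0317, adjusted p = 0.0357). Each gene group described here compares these same arrays.

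**Figure D2:**
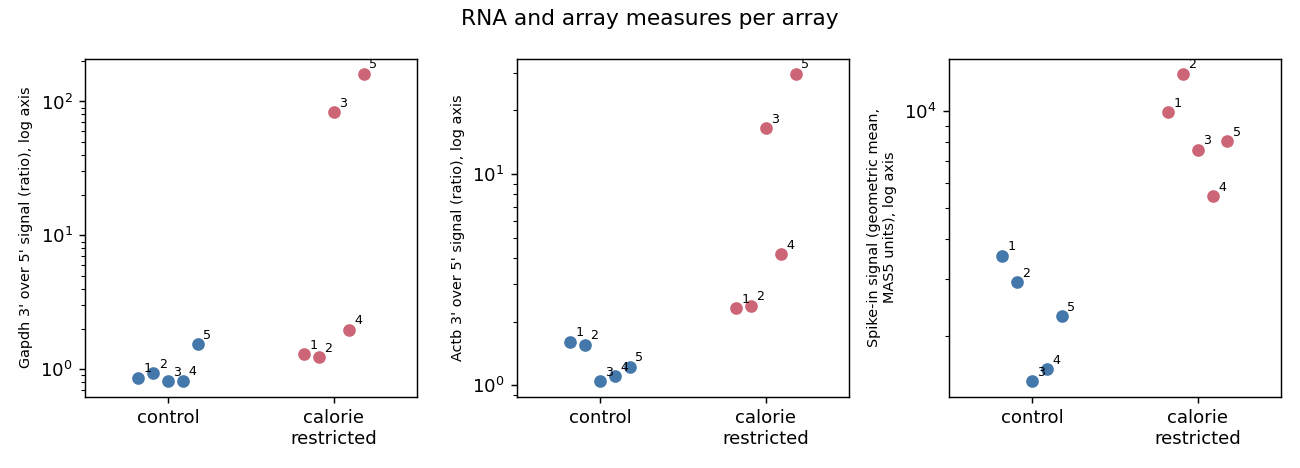
Ratio of 3' to 5' control signal for Gapdh and Actb and geometric mean of the bacterial spike-in signals, on log axes, with 1 point per array numbered by replicate. Calorie restricted replicates 3 and 5 had Gapdh ratios of 82.7 and 160.7, and all 5 calorie restricted arrays lay above all 5 control arrays for Actb and the spike-ins.

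Over the whole array, 883 of 7453 probe sets passed, 306 higher and 577 lower in calorie restricted mice, and they named 731 genes. With 1 array left out the count ran from 253 to 1251: it was 421, 253, 274, 301 and 553 without control replicates 1 to 5, and 349 and 561 without calorie restricted replicates 3 and 4. At an unadjusted p under 0.05 there were 2352. The groups did not overlap in 1067 tested probe sets, or 14.3%, where chance gives 0.794%. Scaling set the balance of directions: under quantile normalization 601 passed, 322 higher and 279 lower. The median log2 change was -0.42 in the dimmest 1491 tested probe sets and 0.13 in the brightest 1491, and 166 of the 306 higher ones lay in the latter. With RNA quality as a covariate 333 passed, of which 181 were among the 883 in the same direction, and the median size of change of the 883 went from 1.06 to 0.77. With RNA quality and spike-in signal together 0 passed in limma, with 907 at an unadjusted p under 0.05. That fit hardly separates diet from the covariates (R2 of diet on both 0.85).

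**Figure D3:**
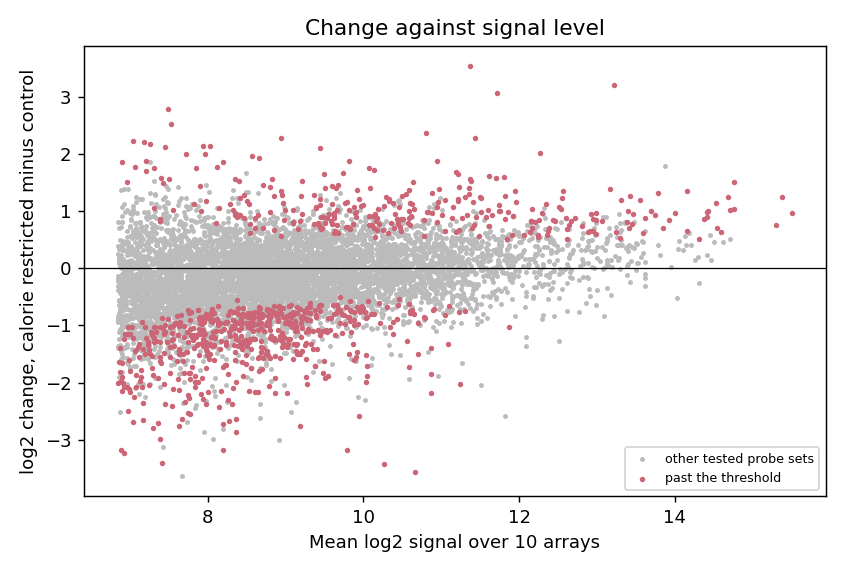
Log2 change between diets against the mean log2 signal over 10 arrays for the 7453 tested probe sets, with the 883 past the threshold in colour. Probe sets past the threshold with low signal were mostly lower in calorie restricted mice and those with high signal mostly higher.

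Genes of oxidative phosphorylation, the respiratory chain and ATP synthase, were higher as a group in calorie restricted mice. Of 30 measured genes of complexes II to V, 8 rose, 1 fell and 21 did not pass, or 12 and 1 past the threshold when adjusted over the list alone. Atp5e, an ATP synthase subunit, changed by 1.66 ± 0.21 (SE), Cox6a1, of cytochrome c oxidase, by 1.51 ± 0.24 and Uqcrc2, of complex III, by 1.42 ± 0.25. Uqcrq, Cox7a2, Atp5d, Uqcrh and Uqcr10 rose by 0.80 to 1.18 on the log2 scale, while Cox6b1 fell by 0.79. The list's median change was 0.69 (camera in limma, adjusted p = 7.97e-06; adjusted p = 0.805 with an estimated correlation; adjusted p = 0.0469 by fry). Another probe set of Atp5d passed in the opposite direction. The probe sets used for Atp5e, Cox6a1, Uqcrc2, Atp5d and Cox6b1 can match several transcripts or rest on fewer probes.

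Of 26 genes of complex I, 5 rose, 0 fell and 21 did not pass, or 8 and 0 when adjusted over the list alone. Ndufc1 changed by 1.71 ± 0.25 (SE), Ndufa5 by 1.51 ± 0.31, Ndufb5 by 1.16 ± 0.26, Ndufa6 by 1.10 ± 0.26 and Ndufb7 by 0.74 ± 0.14. Those of Ndufa5 and Ndufb5 come from probe sets that can match several transcripts or rest on fewer probes. The median was 0.48 (camera in limma, adjusted p = 0.00289; adjusted p = 0.805 with an estimated correlation), and the list did not pass by fry (adjusted p = 0.101). Both lists missed the threshold under quantile normalization, with medians of 0.26 and 0.15 for complexes II to V and complex I (limma camera adjusted p = 0.138 and 0.465). Both passed without calorie restricted replicates 3 and 5, with medians of 0.42 and 0.32 (adjusted p = 5.50e-04 and 0.00769). With RNA quality as a covariate their medians were 0.37 and 0.35 and both passed (adjusted p = 0.00986 and 0.0303), and with spike-in signal added they were 0.05 and 0.17 and neither did (adjusted p = 0.810 and 0.847).

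**Figure D4:**
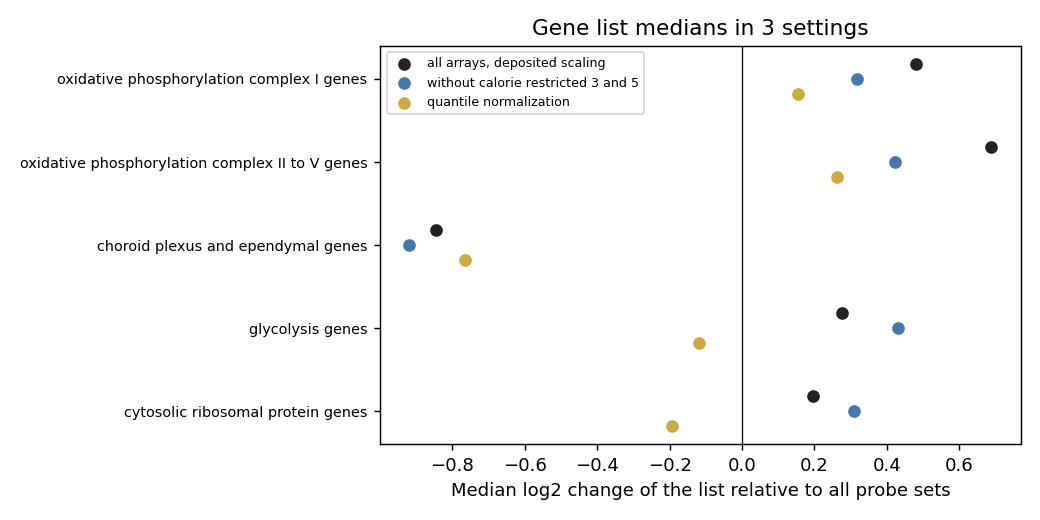
Median log2 change of 5 gene lists relative to all tested probe sets, for all arrays with the deposited scaling, without calorie restricted replicates 3 and 5, and under quantile normalization. The list for complexes II to V had medians of 0.69, 0.42 and 0.26 in these settings, and the glycolysis and ribosomal lists had medians below 0 under quantile normalization.

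None of the other 43 lists passed, with camera adjusted p from 0.0809 to 0.975 in limma. With an estimated correlation 0 of 45 lists passed, with 0 at an unadjusted p under 0.05, and 7 passed by fry in limma, which does not compare a list with other genes. With RNA quality and spike-in signal as covariates 7 lists passed, though none of them did on all arrays without covariates: brain endothelial genes had a median of 1.32, interferon response 1.33, pericyte 1.18, fibroblast 0.91, ribosomal 0.80, autophagy and lysosome 0.59 and thyroid hormone response 0.46. Without covariates these medians were 0.37, 0.063, -0.40, -0.084, 0.19, 0.14 and 0.014, so the pericyte and fibroblast lists turned direction. With RNA quality alone the autophagy and lysosome list passed at 0.275 (limma camera adjusted p = 0.0303), and so did the ribosomal list. Among 7 choroid plexus and ependymal genes, the folate receptor Folr1 changed by -1.36 ± 0.35 (SE) and the ciliary regulator Foxj1 by -0.84 ± 0.28, and both fell. Ttr, the transthyretin transcript of choroid plexus, had -1.89 ± 0.96 and Cox8b had -0.76 ± 0.33, and neither passed. The list's median was -0.84 (camera in limma, adjusted p = 0.0809), and -0.92 without calorie restricted replicates 3 and 5, where the list passed (adjusted p = 0.0377; adjusted p = 0.805 for all arrays with an estimated correlation). It also passed with RNA quality as a covariate, at -1.12 (adjusted p = 0.0302). It did not pass under quantile normalization (adjusted p = 0.138) or with both covariates, where its median was 0.030 (adjusted p = 0.847). Adjusted over the list alone, 3 of its genes fell.

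Astrocyte transcripts included 4 that fell and 0 that rose among 11 measured, or 5 and 0 when adjusted over the list alone. Besides Atp1b2, these were Fgfr3 at -1.96 ± 0.47 (SE), the bicarbonate transporter Slc4a4 at -1.19 ± 0.36 and the water channel Aqp4 at -1.39 ± 0.44. With RNA quality as a covariate Fgfr3, Slc4a4 and Aqp4 had -2.05, -0.42 and -0.62 and did not pass (limma adjusted p = 0.0669, 0.301 and 0.329). With both covariates Aqp4 had 0.26 and the median of the astrocyte list went from -0.17 to 0.35. Of 7 reactive astrocyte genes, 1 fell, the serine protease inhibitor Serpina3n at -1.13 ± 0.22, or 2 when adjusted over the list alone. Among 10 microglial genes the fractalkine receptor Cx3cr1 changed by -0.95 ± 0.22 and the lysosomal Cd68 by -0.71 ± 0.20, and 8 did not pass, among them complement C1qb at -0.86 ± 0.43. Adjusted over the list alone, 1 rose and 2 fell. Of 12 oligodendrocyte and myelin genes, Cldn11, Mal and Ugt8a fell by 0.64, 0.47 and 1.71, and 9 did not pass. Adjusted over the list alone, 1 rose and 5 fell. For the 1 that rose, all 3 other tested probe sets of the gene had the opposite direction and passed. The limma camera adjusted p of these lists was 0.543, 0.151, 0.706 and 0.560 in this order.

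Neuronal transcripts moved both ways. Syt1, the calcium sensor of synaptic vesicles, changed by -3.40 ± 0.72 (SE), with an SD of 1.96 in calorie restricted and 0.14 in control mice, and by -2.26 without calorie restricted replicates 3 and 5. With RNA quality as a covariate Syt1 had -1.76 and did not pass (limma adjusted p = 0.0660). The RNA-binding protein transcript Elavl2 changed by -1.73 ± 0.35 and the neurofilament Nefl by -1.01 ± 0.32, while the surface glycoprotein Thy1 rose by 0.79 ± 0.17. Thy1 had 0.23 under quantile normalization and did not pass there, without replicates 3 and 5 or with RNA quality as a covariate (limma adjusted p = 0.389, 0.0702 and 0.233). Of 14 pan-neuronal genes 1 rose and 4 fell, or 3 and 4 adjusted over the list alone; the median was 0.29 and the mean -0.27. Among 9 genes of glutamatergic neurons Nptx1 and Neurod6 fell by 1.73 and 1.11 and Tbr1 rose by 1.37; adjusted over the list alone, 2 rose and 2 fell. Of 11 interneuron genes, Npy, the vesicular GABA transporter Slc32a1 at 1.06 ± 0.20 and Pvalb at 0.79 ± 0.18 rose and Nxph1 fell, with a log2 signal of 5.30 in calorie restricted mice. Pvalb had 0.35 under quantile normalization and did not pass (limma adjusted p = 0.237). Adjusted over that list alone, 5 rose and 1 fell. Camera adjusted p in limma was 0.635, 0.975 and 0.542 for the 3 lists.

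Of 11 voltage-gated calcium and potassium channel genes, 1 rose and 5 fell, or 1 and 6 adjusted over the list alone. Cacna1g, a T-type calcium channel, was higher in calorie restricted mice, with a log2 signal of 8.28 against 6.08 in control mice, where it lay below the lowest mean tested. Kcna1 changed by -2.01 ± 0.49 (SE), Cacna2d1 by -1.53 ± 0.38 and Cacnb2 by -1.22 ± 0.27. The list's median was -0.69 (camera in limma, adjusted p = 0.123; adjusted p = 0.805 with an estimated correlation). Among 16 neurotrophin and neuropeptide genes, Npy and Chgb rose, the latter by 1.35, and Trh and Pdyn fell by 1.09 and 0.77. Adjusted over the list alone, 5 rose and 2 fell (limma camera adjusted p = 0.378).

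Stress and metabolic genes were also mixed. Of 20 Nrf2 antioxidant genes 5 rose and 2 fell, or 6 and 5 adjusted over the list alone (limma camera adjusted p = 0.542). Sod1 rose, the glutathione peroxidase Gpx1 fell by 0.55 ± 0.15 (SE) and Srxn1 fell by 0.81 ± 0.21. Gstm5 rose by 1.15 ± 0.24, while all 3 of its other tested probe sets had the opposite direction and 1 of them passed. The other probe set of Srxn1 had the opposite direction and did not pass. Of 18 endoplasmic reticulum stress genes, Xbp1 at -1.06, Atf3 at -0.72 and the chaperone Hspa5 at -0.56 fell and Hsp90b1 at 0.83 rose. In that list 1 rose and 4 fell, or 4 and 7 adjusted over the list alone (limma camera adjusted p = 0.560). Of 16 genes of fatty acid oxidation and ketone bodies, 0 rose and 4 fell: Acads, Ppara, Etfdh and Cpt2 fell by 0.62, 0.57, 0.66 and 0.51. Before the median change was taken off, which is what the calls test, these were -0.77, -0.72, -0.81 and -0.66. Adjusted over the list alone, 1 rose and 4 fell; the list's median was 0.15 and its test pointed down (limma camera adjusted p = 0.757).

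Among 13 circadian clock genes, the transcription factor Dbp at 1.51 ± 0.26 (SE) and the repressor Cry1 at 1.23 ± 0.24 rose and Cry2 at -1.03 ± 0.35 fell, with the same counts of 2 and 1 adjusted over the list alone (limma camera adjusted p = 0.635). Of 15 immediate early genes Egr1 and Fos rose by 1.18 ± 0.22 and 1.17 ± 0.30 and 13 did not pass; adjusted over the list alone, 2 rose and 1 fell (limma camera adjusted p = 0.706). With all probe sets of a gene averaged, Egr1 and Fos changed by -0.063 and -0.025. Of 20 glucocorticoid response genes, Glul, which encodes glutamine synthetase, and the metallothionein Mt2 rose by 2.02 ± 0.30 and 0.81 ± 0.19 and the phagocytic receptor Mertk fell by 0.78 ± 0.21. Another probe set of Glul passed in the opposite direction. Adjusted over the list alone, 2 rose and 3 fell (limma camera adjusted p = 0.757).

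Ribosomal protein transcripts Rps28, Rps24 and Rpl19 rose by 1.29, 1.18 and 0.86, out of 14 measured, and 4 rose when adjusted over the list alone. Under quantile normalization the 3 genes had 0.44, 0.25 and 0.26 and did not pass (limma adjusted p = 0.0825, 0.314 and 0.372). The other probe sets of Rps24 and Rpl19 had the opposite direction and did not pass. The median of the list was 0.19, and -0.19 under quantile normalization (limma camera adjusted p = 0.123 and 0.614). The list passed without calorie restricted replicates 3 and 5, with RNA quality as a covariate and with both covariates, with medians of 0.31, 0.45 and 0.80 (limma camera adjusted p = 0.0132 and 0.00986 for the first 2; adjusted p = 0.805 for all arrays with an estimated correlation). Without replicates 3 and 5 under quantile normalization it did not pass (median 0.023, adjusted p = 0.936). Without replicates 3, 4 and 5 its adjusted p was 0.00385. Of 30 proteasome genes, Psmd1, Psmd7 and Psme1 rose by 1.45, 1.04 and 0.88 and Psmb5 fell by 0.999, with the same counts of 3 and 1 adjusted over the list alone (limma camera adjusted p = 0.0809). Of 29 autophagy and lysosome genes, Npc1 and Lamp1 rose by 0.91 and 0.75 and Atg4b fell by 1.08; adjusted over the list alone, 3 rose and 1 fell (limma camera adjusted p = 0.542). Glycolysis genes had 0 of 15 past the threshold and a median of 0.28, or -0.12 under quantile normalization (limma camera adjusted p = 0.217 and 0.798). The glycolysis list passed without calorie restricted replicates 3 and 5 and with RNA quality as a covariate, with medians of 0.43 and 0.53 (limma camera adjusted p = 0.00467 and 0.00318; adjusted p = 0.805 for all arrays with an estimated correlation). Without replicates 3 and 5 under quantile normalization it did not pass (median 0.031, adjusted p = 0.604). It also passed without replicates 3, 4 and 5 (adjusted p = 0.00370), but not with both covariates (median 0.52, adjusted p = 0.0594). Leaving out replicates 3 and 5 moved the log2 change by a factor over 1.5 for 9 of the 97 named genes: Syt1, Slc4a4, Ndufb5, Uqcr10, Gstm5, Psmd7, Cacna2d1, Chgb and C1qb. Of these Uqcr10 and Chgb no longer passed (limma adjusted p = 0.0713 and 0.0536).

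Of the 94 named genes that passed, 37 also passed with RNA quality as a covariate. These were the 24 genes of the main comparison and Elavl2, Nptx1, Neurod6, Nxph1, Serpina3n, Cldn11, Glul, Dbp, Egr1, Ndufc1, Ndufb7, Cox6a1 and Psmd1. Under quantile normalization 30 no longer passed: Rpl41, Thy1, Neurod6, Pvalb, Cd68, Ugt8a, Foxj1, Pdyn, Mertk, Mt2, Cry2, Ndufb7, Ndufb5, Cox6a1, Uqcrq, Cox7a2, Uqcrh, Uqcr10, Cox6b1, Ppara, Etfdh, Cpt2, Atf3, Hsp90b1, Gstm5, Rps28, Rps24, Rpl19, Lamp1 and Chgb. A lost call was not always a smaller change: Neurod6 had -1.11 in both settings, while Rpl41 went from 1.41 to 0.29. Without calorie restricted replicates 3 and 5 those that no longer passed were 21: Thy1, Pvalb, Ugt8a, Folr1, Foxj1, Pdyn, Mt2, Cry2, Fos, Ndufa6, Uqcrh, Uqcr10, Cox6b1, Ppara, Etfdh, Cpt2, Hsp90b1, Psme1, Atg4b, Cacna1g and Chgb.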

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

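The fits without replicates 3 and 5 or with both covariates, the correlation over probe sets called without replicates 3, 4 and 5, and the tests of antisense signal were chosen after the result was seen; quantile normalization and RNA quality as a covariate were settings chosen before, but their use as tests here came after. The verdict on RNA degradation for antisense signal was set after all its values were seen. The splits, the first correlation and the matched random lists were fixed before.

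The first pattern is the 883 probe sets that differed between diets, or 253 to 1251 with 1 array left out. Of 100 splits of the arrays into 5 and 5, 1, the real one, gave as many, and the highest of the others gave 1, which argues against chance. The other splits mix arrays of both diets, so any difference between the groups adds to their spread and few calls were likely there. Nor do the splits tell diet from array quality. Degradation of calorie restricted replicates 3 and 5 as the whole cause is argued against by the 571 of 883 that passed in the same direction without them, and the signal distribution by the 481 that did so under quantile normalization. A smaller loss of integrity on the other arrays may contribute and cannot be told apart from diet. Across the 883, changes of replicates 1 and 2 correlated with the difference of 3 and 5 from 4 at r = 0.45. That was above the bound set beforehand, but those probe sets were chosen with the same arrays. Among the higher and the lower ones r was 0.015 and 0.097. Splitting by direction narrows the range of changes, so low values were likely there. The median difference of 3 and 5 from 4 was 0.46 in the higher and -0.19 in the lower ones. Over all 7453 r was -0.02, and over the 558 called without replicates 3, 4 and 5 it was 0.066. The higher and lower of these 558 had medians of 0.23 and -0.05. The first principal component, with 49.6% of the variance, followed the 3' to 5' difference at r = 0.978 over all arrays. It did so at 0.988 over the 8 without replicates 3 and 5, where diet differs too. Within each diet, the array with the highest 3' to 5' difference also had the highest score, and the lowest had the lowest. With RNA quality as a covariate 181 stayed past the threshold, and with spike-in signal added 0 did, as the median SE grew from 0.25 to 0.52 and the median size of change went from 1.06 to 0.79; an effect of diet stays open.

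The second pattern is the higher oxidative phosphorylation genes. By the bound set beforehand, a rise of all abundant transcripts as the whole cause is argued against for complexes II to V. Their median lay at percentile 99.98 of 10000 random lists matched on mean signal. For complex I, at percentile 95.8 and inside that bound, such a rise is not argued against. The random genes were drawn 1 by 1, so these lists lack correlation between genes and the percentiles may be too extreme. A rise of all abundant transcripts may account for part in both. Under quantile normalization, which removes the shift with signal level, the median for complexes II to V went from 0.69 to 0.26. That list no longer passed there (adjusted p = 0.138 in limma camera, and 0.265 without replicates 3 and 5). Degradation of replicates 3 and 5 as the whole cause is argued against by adjusted p = 5.50e-04 and 0.00769 in limma camera without them, though with an estimated correlation neither list passed on all arrays (adjusted p = 0.805 for both). A smaller loss of integrity may contribute for complexes II to V, whose median difference of replicates 3 and 5 from 4 lay at percentile 98.8 of matched lists, and for complex I, at percentile 76.5, it cannot be told apart because the value lies inside both bounds. With RNA quality as a covariate both lists passed (adjusted p = 0.00986 and 0.0303 in limma camera), and with spike-in signal added neither did (adjusted p = 0.810 and 0.847, medians 0.05 and 0.17); an effect of diet stays open.

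The third pattern is the signal of antisense control probe sets, which by itself did not pass, at 2.63-fold for Actb and 3.80-fold for Gapdh (exact permutation p = 0.175 and 0.0556). The 3' Actb antisense probe set lay 3.38 higher on the log2 scale in calorie restricted mice relative to its sense partner on the same array (exact permutation p = 0.00794). This argues against a rescaling of dim arrays that acts equally on both probe sets. Background was not analysed, so rescaling cannot be excluded where antisense signal may lie near background (30.1 to 327 for Actb in control mice). Lower sense signals of replicates 3 and 5 (12870 and 6171, against 22050 to 31780 in control mice) add to the difference. The same difference between diets for Gapdh was 1.38 (exact permutation p = 0.0556). RNA degradation cannot be told apart from diet: the mean antisense log2 signal of calorie restricted replicates 1 and 2 was 2.02 above that of the more degraded 3 and 5, which met the bound for arguing against it, but relative to the sense partner this difference between replicates was 0.19 for Actb, with overlap, and 1.80 for Gapdh, without, and the less degraded replicate 4 had less antisense signal than 3 for both genes (654 against 1268 for Actb) but more than 5 for Actb (428). A difference in labelling or hybridisation, or an effect of diet, could remain, and no batch is given in the sources used here to test it.

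Other signals outside the main measurement were above the control mice on all 5 calorie restricted arrays: the bacterial spike-in probe sets at 3.79-fold and the probe set for the B1 repeat at 2.18-fold (exact permutation p = 0.00794 for both).

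Single arrays stood apart from the other 4 of their group in 12 of 212 checks, where chance gives about 10.6. The gap to the nearest array was 0.774 of the group's range for the Gapdh 3' to 5' difference and 0.935 for the Actb antisense difference, both in control replicate 5. That array also stood high for Atp5d (0.721) and Fos (0.789). Calorie restricted replicate 5 stood low for Ptbp2 (0.724), Cox8b (0.783) and Aqp4 (0.885) and high for Rps24 (0.736). Calorie restricted replicate 3 stood high for Rpl19 (0.774) and replicate 4 high for Folr1 (0.791). Control replicate 2 stood low for Foxj1 (0.723) and replicate 4 low for Ttr (0.717).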

How the results depend on the processing

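The alternatives that left out several arrays or used spike-in signal were chosen after the data were seen. No probe set among the 883 was called in the opposite direction in any alternative with probe sets as the unit. Their number was within 1.5 times 883 without a filter, at the 60th percentile, with an offset of 32, without the trend, with a robust trend and with array weights. The lower count was 279 under quantile normalization and 378 at the 60th percentile. Arrays centred on their median gave 849 higher and 190 lower. RNA quality as a covariate gave 333 (155 and 178), of which 181 were among the 883, a threshold of 0.10 gave 1627 (572 and 1055), and genes averaged over their probe sets gave 474 (169 and 305). Leaving out calorie restricted replicates 3, 4 and 5 gave 558, with 352 lower, and leaving out 3 and 5 under quantile normalization gave 390 (179 and 211). With RNA quality and spike-in signal as covariates 0 were higher and 0 lower in limma, against 907 at an unadjusted p under 0.05. Fewer samples or more terms may account for part of this in the fits that have them, though leaving out calorie restricted replicate 2 gave 1251. The cause was not tested.

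The fit with a replicate block gave 540 (195 higher and 345 lower), of which 510 were among the 883. The numbers did not pair the arrays: residual correlations of arrays with the same number were -0.08, 0.05, -0.06, 0.02 and 0.17, and 0 control arrays correlated best with their own number.

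Leaving out 1 array gave 253 to 1251 probe sets, 110 to 412 higher and 143 to 839 lower. There were 421, 253, 274, 301 and 553 without control replicates 1 to 5, and 349 and 561 without calorie restricted replicates 3 and 4.

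The number of lists past the threshold was 2, and 2 to 4 with 1 array left out; it was 4 without calorie restricted replicate 5. It was 0 under quantile normalization, with and without calorie restricted replicates 3 and 5 (8 at an unadjusted p under 0.05 in limma camera in each), and 0 with an estimated correlation (also 0 unadjusted). It was 6 with arrays centred on their median or RNA quality as a covariate, 4 with array weights or a threshold of 0.10, 7 by fry, 5 without replicates 3 and 5 or 3, 4 and 5, and 7 with both covariates. The cause was not tested. All 9 array measures kept their direction and side of the threshold on the linear scale.

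Of 97 named genes 94 passed, and 77 of these kept their direction in every alternative that measured them. Averaged over all probe sets of a gene, the direction turned for Slpi (0.025), Atp5d (-0.12), Gstm5 (-0.34), Egr1 (-0.063), Fos (-0.025) and Rpl19 (-0.025). With both covariates it turned for Cox7a2 (-0.067), Uqcrh (-0.0092), Folr1 (0.16), Foxj1 (0.030), Xbp1 (0.15), Cacna1g (-0.0070), Aqp4 (0.26), Tbr1 (-0.0059), Cd68 (0.11), Psmb5 (0.094) and Chgb (-0.19), and 0 of the 94 passed. The cause was not tested, and the fit with both covariates hardly separates diet from them (R2 of diet on both 0.85). Among the 94, 64 passed under quantile normalization, 73 without calorie restricted replicates 3 and 5, 37 with RNA quality as a covariate, and 48 to 93 with 1 array left out. Signal over background was not analysed here.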

Other observations

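The gene families here were grouped by name and tested after the data were seen, 19 in all, of which 5 passed. Genes with Hox names, mostly homeobox genes that pattern the embryonic body axis, had lower signals as a group in calorie restricted mice. The median change of 11, an antisense transcript among them, was -0.60, with 2 lower and 0 higher past the threshold (camera in limma, adjusted p = 0.00914; adjusted p = 0.325 with an estimated correlation). Keratin genes, which encode intermediate filaments of epithelia, had a median of -0.58 over 18, with 7 lower and 0 higher (adjusted p = 0.00914; adjusted p = 0.325 with an estimated correlation). Both families kept their direction under quantile normalization, at adjusted p = 0.0403 and 0.0363 in limma camera. Their medians lay at percentiles 1.63 and 0.07 of 10000 random lists matched on mean signal, whose genes were drawn 1 by 1 and so lack correlation. The Hox probe sets had a median log2 signal of 7.54, against 8.98 over all genes tested. Detection calls were not analysed, so whether the Hox and keratin transcripts were expressed here was not tested.

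Genes for small nuclear ribonucleoproteins and Lsm proteins, which act in splicing and RNA turnover, were higher as a group, with a median of 0.30 over 16 and 3 higher and 0 lower (camera in limma, adjusted p = 0.0385; 0.0403 under quantile normalization; adjusted p = 0.325 with an estimated correlation). Their median lay at percentile 91.4 of matched random lists. Potassium channel genes of the Kcn family had a median of -0.47 over 21, with 4 lower and 0 higher (limma camera adjusted p = 0.0372; adjusted p = 0.325 with an estimated correlation). Without calorie restricted replicates 3 and 5 the Kcn family did not pass (adjusted p = 0.0909). Proteasome genes of the Psm family had a median of 0.29 over 34, with 2 higher and 1 lower (limma camera adjusted p = 0.0385; adjusted p = 0.506 with an estimated correlation). They did not pass under quantile normalization (adjusted p = 0.478) or without replicates 3 and 5 (adjusted p = 0.110), and the proteasome list fixed beforehand did not pass.

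Probe sets of 1 gene often differed. For 107 genes past the threshold with other tested probe sets, 78 of the 126 others had the same direction, or 61.9% (exact Clopper-Pearson 95% interval 52.8 to 70.4%). Of these others 24 passed in the same direction and 7 in the opposite one. The interval treats the 126 probe sets as independent. Some of them share a gene and all were measured on the same arrays, so it does not cover their full uncertainty. The share with the same direction by chance was not computed, so whether 61.9% lies above it was not tested.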
